A study of Mus musculus with 12 samples.

How the data were processed

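RNA was sequenced from 12 subcutaneous tumors of Hep3B, a human hepatocellular carcinoma cell line, grown in BALB/c nude mice. The 4 groups held 3 tumors each, from separate mice: vehicle, H3B-6527 at 300 mg/kg, lenvatinib at 10 mg/kg, and both agents together. Agents were given by oral gavage once a day from a mean tumor volume of about 500 mm3, and tumors were taken 8 hours after dose 4. Each library was run on 4 lanes. The labels give no batch and no pairing of animals between groups, so neither entered a test.

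The deposited table holds expected counts, the estimated count of reads per gene that kallisto assigns, which the authors summed to gene symbols and left unscaled. Of its values, 40.3% were not whole numbers. STAR and kallisto are named in the submitters' processing notes, together with the builds GRCh37 (human) and GRCm38 (mouse). Versions, roles of the builds, annotation and filters were not given in the sources used here. The series is labelled as mouse, but the table lists 36292 human gene symbols, and 9253 of these had no counts in any library. Mouse genes and the mouse share of reads, planned as separate comparisons, were therefore not analysed here. Whether reads from mouse cells were removed before quantification is not known from these sources, and reads of host origin could add to conserved human genes. No human annotation was used, so gene coordinates, lengths and GC content are not reported.

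Counts were rounded to whole numbers. Genes were kept by filterByExpr on the 4 groups, which left 15836. Differential expression was tested with edgeR 4.0.16 (TMM factors, robust dispersion, quasi-likelihood F-test, 2-sided) in R 4.3.3, with all 12 libraries in 1 fit. P-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison, and the threshold was 0.05. Fold changes are log2 values with their SE, and expression levels are CPM, edgeR's count per M (mega) of the library total times its TMM factor, as mean ± SD of 3 tumors. The 6 pairs of groups were compared, and a contrast of combination minus both single agents plus vehicle tested non-additivity on the log2 scale.

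Gene lists were tested with camera in limma 3.58.1 on voom values with the preset correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list's members differ from the other genes. Each list was tested again with a correlation estimated from these libraries, and with fry, which asks whether a list moves on balance one way and does not set it against other genes. For each list the members past the threshold over all genes tested are given beside the number adjusted over the list alone. The 24 tumor lists covered FGFR-MAPK output, bile acid synthesis, FXR targets and bile acid transport, S phase, G2 and mitosis, CDK inhibitors and quiescence, BCL2 family, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPAR targets, hypoxia, integrated stress response, ER chaperones, interferon response, hepatocyte products, acute phase, receptor tyrosine kinases, FGF and VEGF family ligands, WNT targets, YAP targets, immediate early genes, heat shock, epithelial-mesenchymal genes and the mitochondrial genome. Mouse cell-type markers were looked up as human symbols. Lists for endothelial cells, endothelial tip cells, lymphatic endothelium, pericytes and smooth muscle, fibroblasts, macrophages and skeletal muscle had 5 or more tested members, and the others had too few to test.

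Comparisons, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took 3 kinds of gene. It took the 10 largest rises and the 10 largest falls of a comparison with adjusted p under 0.05, an absolute log2 fold change of 1 or more, mean log2 CPM of 1 or more, and all 3 tumors of a group above all 3 of the other. It also took 19 genes fixed by name, and up to 4 members of each list with the smallest p. Genes with close paralogs or read-through names among those that qualified are left out of the text.

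Library totals ran from 23.8 to 40.9 M counts. A floor of 3 counts corresponds to 0.126 CPM in the smallest library and 0.073 CPM in the largest. For genes with few counts, 95% intervals of a ratio are exact binomial intervals (scipy 1.17.1). Such intervals and floors cover counting error only. The intervals pool the counts of the 3 tumors of a group and leave out differences between tumors. The libraries also carry no molecular identifiers.

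On simulated data, counts were drawn from the means, spreads and library sizes of the real genes, with no difference between the groups compared except the changes put in. At 2-fold, 71.6% were recovered between H3B-6527 and vehicle, 79.1% between lenvatinib and vehicle and 46.3% in the non-additivity contrast. At 4-fold the shares were 87.9%, 90.9% and 87.9%. These shares hold for the simulated spreads. Real tumors varied more with H3B-6527 than in the other groups. The shares therefore do not tell how many real changes of these sizes were missed.

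Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, no filter, a stricter filter (1 CPM in 3 libraries and 50 counts in all), only the 2 groups compared, and each library left out in turn. Library totals without TMM factors, fits of 3 groups, and the list tests under these settings were chosen after seeing the data. The joint human and mouse library size that was planned could not be run on a table of human genes. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.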

Results

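The series measured gene expression in Hep3B xenograft tumors by RNA sequencing, 3 tumors in each of 4 groups. Group means of the library totals were 35.7 ± 1.24 M (mega) counts with vehicle, 34.4 ± 9.18 M with H3B-6527, an inhibitor selective for the FGF receptor FGFR4, 34.7 ± 3.06 M with lenvatinib, a multikinase inhibitor of VEGF and FGF receptors among others, and 34.9 ± 5.31 M with the combination (SD, n = 3). The smallest library was H3B-6527 replicate 3 with 23.8 M. Albumin (ALB) transcripts made up 3.73 ± 0.10% of counts with vehicle and 4.15 ± 0.49% with lenvatinib, but 7.63 ± 1.42% with H3B-6527 and 7.31 ± 0.43% with the combination. In a principal component analysis, component 1 held 64.8% of the variance. Vehicle and lenvatinib tumors lay between −61.3 and −29.4 on it, and H3B-6527 and combination tumors between 24.2 and 74.8. The 3 H3B-6527 tumors differed more from each other than other replicates did, with a biological coefficient of variation of 21.6% against 8.19% with vehicle, 10.7% with lenvatinib and 11.2% with the combination.

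H3B-6527 against vehicle asks what the FGFR4 inhibitor alone changed in the tumor cells. Genes switched on by FGF receptor and MAP kinase signalling fell. DUSP6, a phosphatase that dampens ERK and is induced by it, fell by 4.01 ± 0.39 on the log2 scale (SE, n = 3 tumors per group, adjusted p = 1.13e-05), from 80.6 to 5.13 CPM. The ERK-responsive transcription factor ETV5 fell by 3.87 ± 0.29 (adjusted p = 2.53e-06) and the growth regulator MYC by 2.78 ± 0.17 (adjusted p = 4.91e-07), from 47.2 to 6.93 CPM. CYP7A1, the rate-limiting enzyme of bile acid synthesis that FGF19 and FGFR4 repress, rose by 6.91 ± 0.63 (adjusted p = 6.95e-06), from 0.087 to 10.9 ± 5.59 CPM (SD). Its 10 counts over the vehicle tumors against 1178 give a 122-fold ratio with a 95% counting interval of 66.3 to 256.

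In the FGFR-MAPK output list, 17 of 20 measured genes fell and none rose, and the number adjusted over the list alone was also 17 (median log2 fold change −2.79, list adjusted p = 2.26e-09, adjusted p = 0.479 with an estimated correlation). SPRY1, a feedback inhibitor of the pathway, fell by 3.36 ± 0.26, SPRY4 by 4.80 ± 0.57, SPRY2 by 2.29 ± 0.23, ETV4 by 2.68 ± 0.43, the early growth response gene EGR1 by 4.58 ± 0.76 and cyclin D1 (CCND1) by 2.07 ± 0.22. DUSP4 fell by 3.26 ± 0.49 (adjusted p = 1.45e-04), from 80 counts over the vehicle tumors to 7, which is 11-fold lower (counting interval 5.10 to 28.2). In the bile acid synthesis list, 11 of 16 genes rose and none fell, with 11 also adjusted over the list alone (median 0.86, list adjusted p = 7.73e-04, adjusted p = 0.515 with an estimated correlation). CYP8B1, which makes cholic acid precursors, rose by 2.74 ± 0.60 (adjusted p = 0.00237), AKR1D1 by 4.69 ± 0.47 and CYP27A1 by 1.51 ± 0.18. The FGF19 co-receptor KLB rose by 2.37 ± 0.20, from 45.7 to 236 CPM. FGFR4 itself fell by 0.28 ± 0.10 (adjusted p = 0.0353), a call lost without vehicle replicate 1 (adjusted p = 0.124), vehicle replicate 3 (0.0991) or H3B-6527 replicate 1 (0.115), and in a fit of the 2 groups alone (0.106) or without the combination group (0.0550, range over all alternatives 0.00626 to 0.124, values from −0.40 to −0.16). FGF19 had a log2 fold change of −0.89 ± 0.38 (adjusted p = 0.0710). It passed in 4 of 14 alternatives, with DESeq2 (0.0458), voom (0.0227), library totals (0.0445) and without H3B-6527 replicate 3 (0.0144). Over all of them the value ran from −1.28 to −0.47 and adjusted p from 0.0144 to 0.159.

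Genes for hepatocyte products rose. In the hepatocyte product list, 20 of 30 genes rose and 1 fell, the same numbers as adjusted over the list alone (median 1.14, list adjusted p = 1.29e-06, adjusted p = 0.489 with an estimated correlation). ALB rose by 1.16 ± 0.17 (adjusted p = 1.30e-04), the heme carrier hemopexin (HPX) by 3.07 ± 0.25, the urea cycle enzyme CPS1 by 2.99 ± 0.28 and alpha-fetoprotein (AFP), a product of fetal liver and liver tumors, by 1.12 ± 0.20. In the fatty acid oxidation list, 16 of 20 rose and 1 fell, as over the list alone (median 0.70, list adjusted p = 2.10e-05, adjusted p = 0.489 with an estimated correlation), among them the peroxisomal enzyme EHHADH by 2.03 ± 0.18. The acute phase list had 8 of 13 genes higher and 1 lower by both counts (median 0.87, list adjusted p = 0.0247, adjusted p = 0.515 with an estimated correlation and 0.0512 in a fit of the 2 groups alone), led by IL6R, the interleukin 6 receptor (1.37 ± 0.20). Of 24 interferon response genes, 9 rose and 1 fell by both counts (median 0.43, list adjusted p = 0.0486, adjusted p = 0.515 with an estimated correlation). IFIT1, an antiviral gene, rose by 2.87 ± 0.28. The interferon call was lost without H3B-6527 replicate 1 (adjusted p = 0.0797), without vehicle replicate 3 (0.0564) and in the 2-group fit (0.0512). Further large rises named by the rule were CYP4F3, a leukotriene hydroxylase (4.77 ± 0.33), and the plasma protein FETUB (4.73 ± 0.49).

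Cell cycle genes fell. In the G2 and mitosis list 28 of 36 genes fell and none rose, or 33 adjusted over the list alone (median −0.81, list adjusted p = 2.00e-08, adjusted p = 0.515 with an estimated correlation). In the S phase list 18 of 35 fell, or 19 over the list alone (median −0.55, list adjusted p = 1.07e-05, adjusted p = 0.553 with an estimated correlation). The spindle checkpoint kinase BUB1B fell by 1.03 ± 0.17 and the nucleotide reductase subunit RRM2 by 1.68 ± 0.24. The proliferation marker MKI67 had a log2 fold change of −0.67 ± 0.26 (adjusted p = 0.0511), from 550 to 346 ± 161 CPM (SD). The spread of the H3B-6527 tumors enters here: without H3B-6527 replicate 3 the MKI67 value was −1.12 (adjusted p = 1.50e-04), and over all alternatives it ran from −1.12 to −0.44 (adjusted p from 1.50e-04 to 0.180). The medians of G2 and mitosis and of S phase were −1.13 and −0.88 without H3B-6527 replicate 3, and −0.59 and −0.36 without H3B-6527 replicate 1.

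Among immediate early genes, transcription factors switched on within minutes by mitogens, 12 of 18 fell, as over the list alone, where 1 also rose (median −1.40, list adjusted p = 1.27e-04, adjusted p = 0.489 with an estimated correlation), FOS by 3.55 ± 0.39. WNT targets had 9 of 17 lower and 2 higher by both counts (median −0.66, list adjusted p = 0.0101, adjusted p = 0.479 with an estimated correlation). Without H3B-6527 replicate 1 the median of WNT targets was −0.40. The stem cell receptor LGR5 fell by 2.66 ± 0.21. YAP targets had 7 of 14 lower and 1 higher, or 8 and 3 over the list alone (median −0.54, list adjusted p = 0.0292, adjusted p = 0.489 with an estimated correlation), and the call was lost without H3B-6527 replicate 2 (adjusted p = 0.0549). Without vehicle replicate 1 the median of YAP targets was −0.27. The matricellular gene CYR61 fell by 2.48 ± 0.15. The integrated stress response list had 12 of 22 lower and 4 higher by both counts (median −0.61, list adjusted p = 0.0247, adjusted p = 0.515 with an estimated correlation), with the pseudokinase TRIB3 down by 2.26 ± 0.20. The largest falls named by the rule included the Notch target HEY1, which fell by 5.75 ± 0.52, and LFNG, a glycosyltransferase that modifies Notch, which fell by 6.29 ± 0.69.

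The other 12 tumor lists did not pass the list test, though members went both ways. Of 31 hypoxia genes, 7 rose and 11 fell, or 7 and 14 over the list alone (median −0.31, or −0.17 without vehicle replicate 2 and −0.42 without vehicle replicate 1, adjusted p = 0.144). The glucose kinase HK2 fell by 2.78 ± 0.22, and VEGFA, the main angiogenic ligand, had a log2 fold change of −0.26 ± 0.14 (adjusted p = 0.128, or 0.0412 with library totals, range 0.0412 to 0.412, values from −0.38 to −0.15). The hypoxia-induced carbonic anhydrase CA9 fell by 2.74 ± 0.87 (adjusted p = 0.0221), but its groups overlapped and the call was lost without vehicle replicate 2 (0.113), H3B-6527 replicate 1 (0.126) or H3B-6527 replicate 2 (0.0754), with voom (0.0648) and without a filter (0.0760, range 0.00632 to 0.126). The CA9 value itself ran from −3.73 without H3B-6527 replicate 3 to −1.32 without vehicle replicate 2. Adjusted p was 0.258 for FXR targets and transport (9 higher and 4 lower of 16, 9 and 6 over the list alone), 0.109 for fatty acid synthesis (6 and 2 of 15) and 0.998 for cholesterol synthesis (7 and 5 of 25), whose median of −0.04 and mean of −0.02 lay opposite to the list test. It was 0.938 for CDK inhibitors (4 and 3 of 16), with a median of 0.02 but a mean of −0.28, 0.40 for the BCL2 family (5 and 7 of 17), 0.405 for ER chaperones (2 and 3 of 16) and 0.236 for heat shock (2 and 6 of 13). It was 0.367 for receptor tyrosine kinases (7 and 8 of 19), 0.0923 for FGF and VEGF family ligands (2 and 5 of 12) and 0.863 for epithelial-mesenchymal genes (5 and 5 of 14, 5 and 7 over the list alone). Where no second pair is given, the numbers over the list alone were identical. FGFR1 fell by 3.61 ± 0.33 and the MET ligand HGF fell by 3.48 ± 0.36. The mitochondrial genome list had 7 of 13 genes lower, or 8 over the list alone (adjusted p = 0.0512), on transcripts that took 0.018% of counts with vehicle and 0.014% with H3B-6527.

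Markers of host cells, looked up under their human symbols, were sparse. Of 26 endothelial genes in the table, 21 had under 1 CPM. The fibroblast list had 5 of 7 genes lower by both counts (median −1.12, adjusted p = 0.0143, adjusted p = 0.098 with an estimated correlation), and PDGFRA, also a member of the receptor tyrosine kinase list, fell by 1.58 ± 0.11. Of the 18 fibroblast genes measured, 13 had under 1 CPM, and over all 12 tumors DCN had 11 counts and LUM 18, against 18663 for PDGFRA. Its values can therefore come from the tumor cells, and no change in fibroblasts is read from them here or below. The fibroblast call was lost without vehicle replicate 1 (adjusted p = 0.0503) and without H3B-6527 replicate 2 (0.0634), and with no low-count filter. Adjusted p was 0.841 for endothelial cells, 0.401 for tip cells, 0.841 for lymphatic endothelium (median 0.28, mean −1.02), 0.742 for pericytes, 0.401 for macrophages and 0.447 for skeletal muscle.

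Over all genes, 3987 rose and 3842 fell with H3B-6527 among 15836 tested, of which 1445 rose and 1192 fell by at least 2-fold. Scaling by library totals alone shifted the median of all genes by −0.12 and changed the split to 3022 higher and 4960 lower. With an estimated correlation 0 of the 24 lists passed the list test, while fry called 17. Of the genes named here that passed the test, CA9 was the only one whose groups of 3 tumors overlapped.

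**Figure D1:**
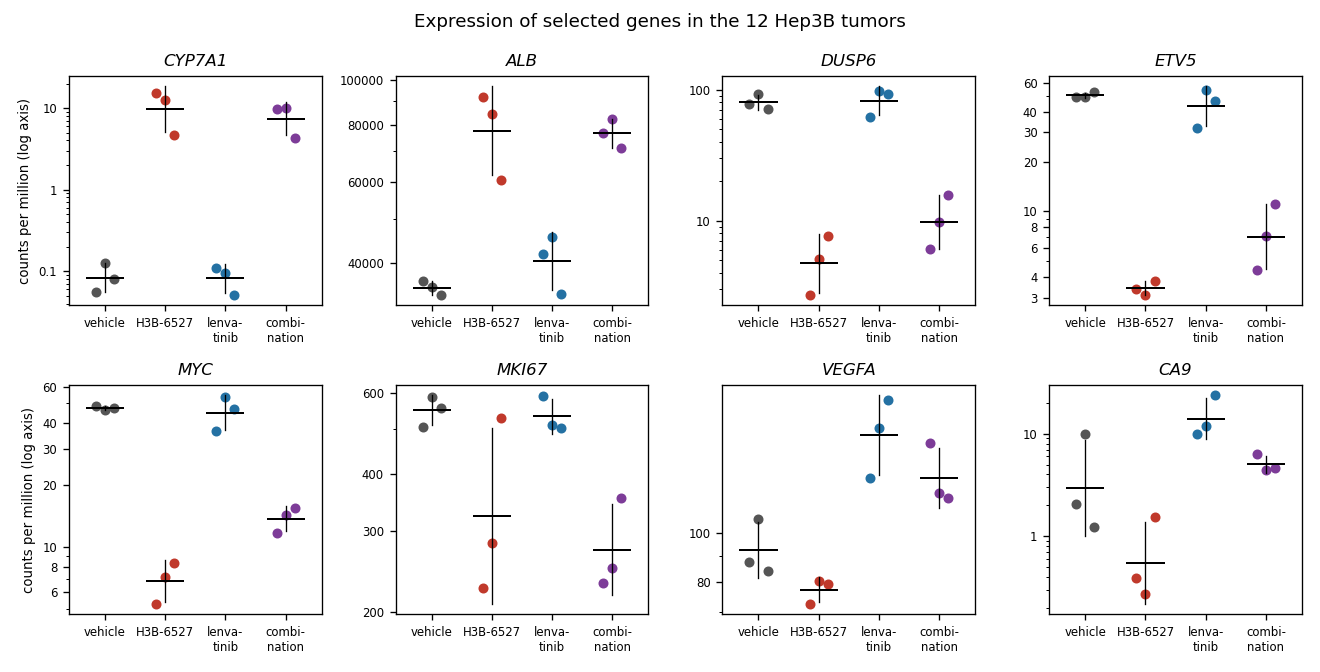
Expression of 8 genes in each tumor, in CPM on a log axis, by group. Each point is 1 tumor, the line is the geometric mean of 3 tumors and the whisker is 1 SD of the log2 values; DUSP6, ETV5 and MYC lie lower, and CYP7A1 and ALB higher, in all H3B-6527 and combination tumors than in any vehicle tumor.

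**Figure D2:**
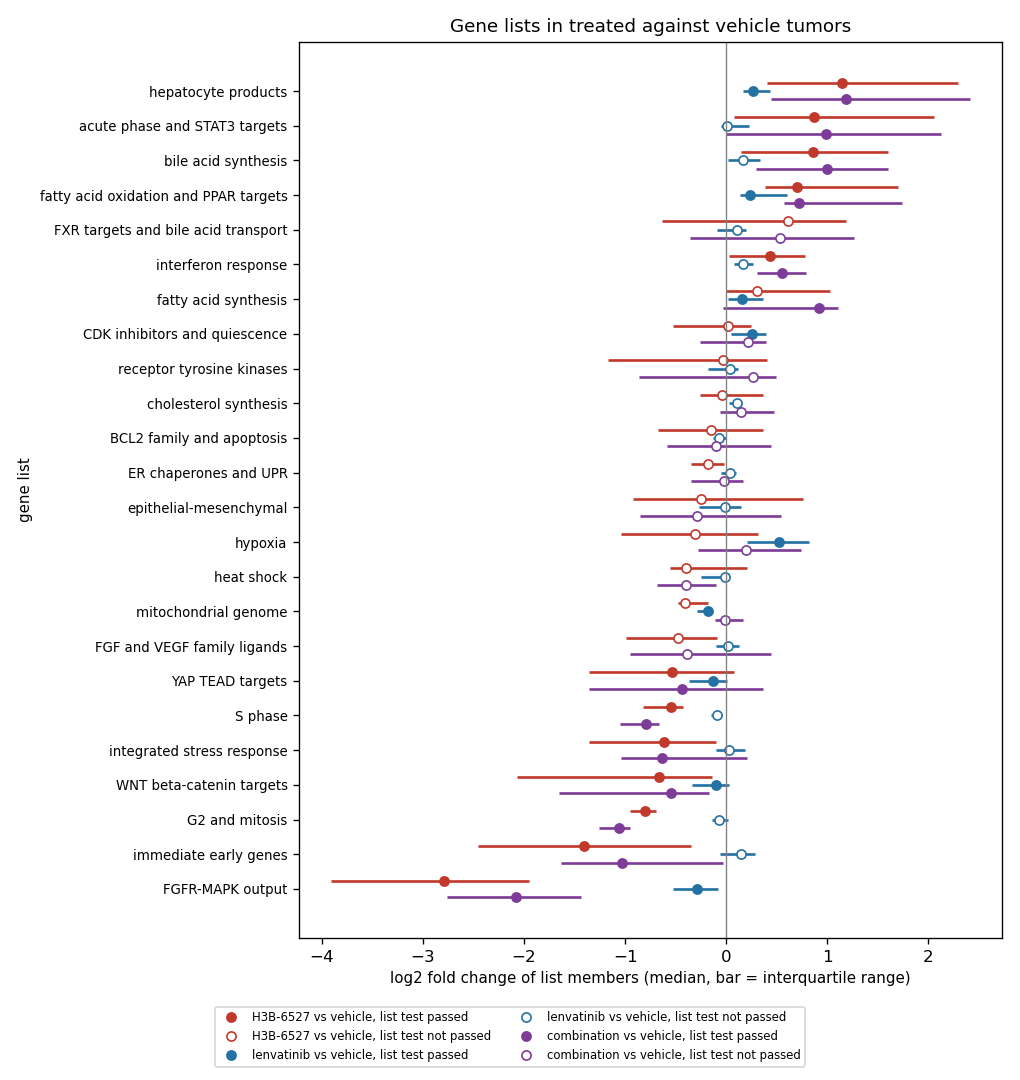
Median log2 fold change against vehicle of the members of 24 gene lists, with bars for the interquartile range over genes, for H3B-6527, lenvatinib and the combination. Filled points passed the list test with the preset correlation and open points did not; the hypoxia list lies at 0.52 with lenvatinib and at −0.31 with H3B-6527 (−0.17 without vehicle replicate 2).

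The combination against vehicle asks what both agents changed together. FGFR-MAPK output genes were again lower and bile acid and hepatocyte genes higher than with vehicle. DUSP6 fell by 2.93 ± 0.36 (SE, n = 3 per group, adjusted p = 5.90e-05) to 10.5 CPM, ETV5 by 2.73 ± 0.27 (adjusted p = 1.35e-05), MYC by 1.77 ± 0.17 (adjusted p = 5.58e-06) and EGR1 by 2.53 ± 0.67 (adjusted p = 0.00922). CYP7A1 rose by 6.43 ± 0.63 (adjusted p = 1.28e-05), a 77.9-fold ratio with a counting interval of 42.1 to 163. CYP8B1 rose by 3.31 ± 0.59 and ALB by 1.12 ± 0.17 (adjusted p = 1.68e-04). VEGFA rose by 0.47 ± 0.14 (adjusted p = 0.0115), from 92.8 to 129 CPM, a call lost without vehicle replicate 3 (adjusted p = 0.0560), without combination replicate 1 (0.0633) and with library totals (0.0740, range over all alternatives 0.00261 to 0.0740).

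Of 20 FGFR-MAPK output genes 18 fell, as over the list alone (median −2.07, list adjusted p = 9.42e-09, adjusted p = 0.363 with an estimated correlation). Bile acid synthesis had 11 of 16 higher and 1 lower by both counts (median 0.99, list adjusted p = 6.34e-04, adjusted p = 0.451 with an estimated correlation). Hepatocyte products had 21 of 30 higher and none lower by both counts (median 1.18, list adjusted p = 9.42e-09, adjusted p = 0.363 with an estimated correlation). The plasma protein HRG rose by 4.69 ± 0.32. Cell cycle genes fell in 35 of 36 cases for G2 and mitosis (median −1.06, list adjusted p = 3.98e-10, adjusted p = 0.451 with an estimated correlation) and in 31 of 35 for S phase (median −0.79, list adjusted p = 7.20e-08, adjusted p = 0.456 with an estimated correlation), as over each list alone. MKI67 fell by 0.99 ± 0.26 (adjusted p = 0.00844) and BUB1B by 1.42 ± 0.17. Fatty acid oxidation had 17 of 20 higher, or 18 higher and 1 lower over the list alone (median 0.72, list adjusted p = 7.45e-07, adjusted p = 0.363 with an estimated correlation), and fatty acid synthesis had 9 of 15 higher and 2 lower by both counts (median 0.91, list adjusted p = 0.0165, adjusted p = 0.451 with an estimated correlation), with the glucose-responsive factor MLXIPL up by 1.40.

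Interferon response genes had 12 of 24 higher and 1 lower (list adjusted p = 0.00709) and acute phase genes 8 of 13 higher and 1 lower (0.0165), both with the same counts over the list alone and adjusted p = 0.451 with an estimated correlation. Immediate early genes had 11 of 18 lower and 1 higher, or 12 and 1 over the list alone (list adjusted p = 0.00709, adjusted p = 0.451 with an estimated correlation). WNT targets had 8 of 17 lower and 3 higher, or 9 and 3 over the list alone (list adjusted p = 0.0162, adjusted p = 0.363 with an estimated correlation). YAP targets had 8 of 14 lower and 3 higher by both counts and the stress response 12 of 22 lower and 3 higher, or 13 and 3 over the list alone (list adjusted p = 0.0484 for each, adjusted p = 0.451 for each with an estimated correlation). Without combination replicate 3 both of these calls were lost (adjusted p = 0.0635 for each), as they were with library totals (0.0825 and 0.0930). The stress response call was also lost without vehicle replicate 3 (0.0637) and the YAP call in the 2-group fit (0.0839). Hypoxia genes went both ways, 10 of 31 higher and 7 lower by both counts (adjusted p = 0.438). The metastasis-suppressor and hypoxia gene NDRG1 rose by 3.18 ± 0.47 while HK2 fell by 2.08. The fibroblast list was lower (median −1.09, adjusted p = 0.0192, adjusted p = 0.118 with an estimated correlation), but not without vehicle replicate 1 (0.0621) or combination replicate 2 (0.0572). In all, 3924 genes rose and 4006 fell, or 2923 and 5339 with library totals, which shifted the median of all genes by −0.15.

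Lenvatinib against vehicle asks what the multikinase inhibitor alone changed. No single gene passed the test with edgeR on all 12 libraries, and the list with the smallest p was hypoxia. VEGFA had a mean of 157 CPM against 92.8 with vehicle (log2 fold change 0.76 ± 0.14, SE, n = 3 per group, adjusted p = 0.0894), with 3 of 3 lenvatinib tumors above every vehicle tumor. Of 31 hypoxia genes 28 had a positive log2 fold change, and 17 passed when adjusted over the list alone, none of them lower (median 0.52, list adjusted p = 9.52e-14, adjusted p = 0.216 with an estimated correlation). NDRG1 had a value of 2.12 ± 0.45 (adjusted p = 0.139), the glycolysis regulator PFKFB4 1.36 ± 0.28 (adjusted p = 0.139), the mitophagy gene BNIP3 0.61 ± 0.12 (adjusted p = 0.124) and CA9 1.78 ± 0.68 (adjusted p = 0.366, below the threshold with voom only, at 0.0199, range over all alternatives 0.0199 to 0.853). The CA9 value ran from 1.30 without lenvatinib replicate 3 to 3.20 without vehicle replicate 2, with 4.40 ± 4.77 CPM (SD) in the vehicle tumors.

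DUSP6 (log2 fold change 0.06 ± 0.33, range over all alternatives −0.06 to 0.24), MYC (−0.06 ± 0.16, range −0.19 to 0.08), MKI67 (−0.04 ± 0.26, range −0.12 to 0.01) and ALB (0.20 ± 0.17, range 0.11 to 0.31) did not pass the test. The FGFR-MAPK output list was lower as a set (median −0.29, 0 of 20 genes past the threshold by both counts, list adjusted p = 1.58e-04, adjusted p = 0.516 with an estimated correlation), a call lost without lenvatinib replicate 1 (adjusted p = 0.0632). The hepatocyte list was higher, with 29 of 30 values positive (median 0.26, list adjusted p = 7.52e-07, adjusted p = 0.310 with an estimated correlation), and so was fatty acid oxidation, with 20 of 20 positive (median 0.23, list adjusted p = 8.63e-06, adjusted p = 0.310 with an estimated correlation). YAP targets were lower (median −0.13, 3 genes over the list alone, list adjusted p = 5.53e-04, adjusted p = 0.216 with an estimated correlation) and CDK inhibitors higher (median 0.25, 2 genes over the list alone, list adjusted p = 0.00646, adjusted p = 0.216 with an estimated correlation). WNT targets (median −0.10, 1 gene over the list alone, list adjusted p = 0.00775, adjusted p = 0.216 with an estimated correlation) and the mitochondrial genome (median −0.19, list adjusted p = 5.53e-04, adjusted p = 0.562 with an estimated correlation) were lower, and both calls were lost without lenvatinib replicate 3 (adjusted p = 0.0602 for each). Fatty acid synthesis (median 0.15, list adjusted p = 0.0441, adjusted p = 0.578 with an estimated correlation) lost its call without vehicle replicate 2 (adjusted p = 0.262) or 3 (0.0708) and without lenvatinib replicate 1 (0.108) or 2 (0.191). These medians are small, and leaving out 1 library moved several by over 1.5 times. FGFR-MAPK output went to −0.11 without lenvatinib replicate 1 and −0.49 without lenvatinib replicate 2. CDK inhibitors went to 0.145 without lenvatinib replicate 2 and YAP targets to −0.20 without vehicle replicate 3. WNT targets went to −0.18 and −0.16 without lenvatinib replicates 1 and 2, the mitochondrial genome to −0.345 and −0.12 without lenvatinib replicates 2 and 3, and fatty acid synthesis to 0.08 without vehicle replicate 2 and 0.25 without lenvatinib replicate 3.

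With edgeR on all 12 libraries 0 of 15836 genes were called, with 1698 at an unadjusted p under 0.05. The smallest adjusted p was 0.0669 for LRP11 (0.59 ± 0.08), a gene singled out after its values were seen. The shared spread of that fit includes the H3B-6527 tumors, which varied most. EdgeR called 189 genes in a fit of the 2 groups alone, 173 without the H3B-6527 group and 0 without the combination group. DESeq2 called 245 genes (128 higher, 117 lower) and voom with quality weights 525 (264 higher, 261 lower). VEGFA passed with DESeq2 (adjusted p = 2.52e-04) and voom (0.00853), in the fit of the 2 groups alone (0.0460) and in 2 other settings, with a range of 2.52e-04 to 0.551.

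The combination against H3B-6527 asks what lenvatinib added to the FGFR4 inhibitor. The hypoxia list was higher, and so was the FGFR-MAPK output list, which H3B-6527 alone had lowered. Both calls were made with the preset correlation (adjusted p = 6.61e-13 and 8.40e-07). Both were lost with an estimated one (adjusted p = 0.327 for each with an estimated correlation). Fry called 0 lists, and no member named here passed the gene test. VEGFA had 129 CPM against 77.3 (log2 fold change 0.73 ± 0.14, SE, n = 3 per group, adjusted p = 0.191), DUSP6 10.5 against 5.13 (1.08 ± 0.38, adjusted p = 0.428), ETV5 7.53 against 3.46 (1.14 ± 0.29, adjusted p = 0.326) and MYC 13.8 against 6.93 (1.01 ± 0.17, adjusted p = 0.145). Without combination replicate 3 the values of DUSP6 and ETV5 were 0.65 and 0.75, and over all alternatives they ran up to 1.46 and 1.41. For VEGFA, ETV5 and MYC 3 of 3 combination tumors lay above every H3B-6527 tumor. CYP7A1 (−0.48 ± 0.38, adjusted p = 0.732, range −0.82 to −0.16), ALB (−0.04 ± 0.17, range −0.19 to 0.08) and MKI67 (−0.32 ± 0.26, range −0.55 to 0.13) did not pass the test.

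In the hypoxia list 27 of 31 values were positive, and 15 genes passed adjusted over the list alone (median 0.60, list adjusted p = 6.61e-13, adjusted p = 0.327 with an estimated correlation). Of the positive values, 24 were positive also with lenvatinib alone against vehicle (24.4 by chance). With 28 of 31 positive there, this overlap was nearly fixed beforehand and does not measure agreement. FGFR-MAPK output had 16 of 20 positive and 4 over the list alone (median 0.64, or 0.425 without H3B-6527 replicate 1, list adjusted p = 8.40e-07), and immediate early genes had 4 over the list alone (median 0.38, list adjusted p = 7.06e-06). Cholesterol synthesis had 25 of 25 positive and 6 over the list alone (median 0.20, list adjusted p = 6.55e-08), and the mitochondrial genome had 1 over the list alone (median 0.36, list adjusted p = 4.09e-07). These 4 lists had adjusted p = 0.327 with an estimated correlation. The hepatocyte list (median 0.18, list adjusted p = 7.00e-04, adjusted p = 0.390 with an estimated correlation) lost its call without H3B-6527 replicate 3 (0.464), where its median was 0.01, and had a median of 0.28 without H3B-6527 replicate 1. Fatty acid synthesis (median 0.12, list adjusted p = 0.00276, adjusted p = 0.340 with an estimated correlation) lost it without combination replicate 2 (0.0780), and its median was 0.18, 0.22 and 0.19 without H3B-6527 replicate 1, H3B-6527 replicate 3 and combination replicate 1. CDK inhibitors (median 0.16, list adjusted p = 0.0133, adjusted p = 0.327 with an estimated correlation) lost it without H3B-6527 replicate 2 (0.138) or combination replicate 2 (0.126).

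The S phase list (median −0.25, list adjusted p = 0.00276) and the G2 and mitosis list (median −0.26, list adjusted p = 0.00292) were lower, each with adjusted p = 0.636 with an estimated correlation. Without H3B-6527 replicate 3 both turned positive (medians 0.04 and 0.11, adjusted p = 0.284 and 0.115), and without combination replicate 1 both calls were lost (adjusted p = 0.371 for each), as was that of G2 and mitosis without combination replicate 2 (0.0757). Without H3B-6527 replicate 1 the medians were −0.44 and −0.45. Without combination replicate 1 they were −0.13 and −0.16, and without combination replicate 3 they were −0.42 and −0.46. That of G2 and mitosis was −0.17 without combination replicate 2. Heat shock genes were lower, 2 over the list alone (list adjusted p = 0.0174, adjusted p = 0.460 with an estimated correlation), a call lost without H3B-6527 replicate 2 (0.494) or 3 (0.0504). FGF and VEGF family ligands were higher, 2 over the list alone (list adjusted p = 0.0180, adjusted p = 0.345 with an estimated correlation), a call lost without H3B-6527 replicate 1 (0.925) or 2 (0.138) and without combination replicate 2 (0.180) or 3 (0.225), where the median turned to −0.01.

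Among single genes edgeR called 2, both higher in 3 of 3 combination tumors than in every H3B-6527 tumor and named after their values were seen: the junctional adhesion molecule JAML (0.88 ± 0.10, adjusted p = 0.0107), at 21.6 CPM against 11.7 with H3B-6527 and 25.4 with vehicle, and the histidine breakdown enzyme AMDHD1 (0.95 ± 0.12, adjusted p = 0.0127), at 27.7 CPM against 14.4 and 43.0. At an unadjusted p under 0.05 there were 1492. DESeq2 called 98 (81 higher, 17 lower), MYC (adjusted p = 5.37e-05, range 5.37e-05 to 0.495), VEGFA (4.91e-04, range 4.91e-04 to 0.438) and ETV5 (0.00897, range 0.00897 to 0.834) among them. Without combination replicate 3 edgeR called 0, and without H3B-6527 replicate 3 it called 16 and MYC passed (adjusted p = 0.0373).

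The combination against lenvatinib asks what H3B-6527 added to lenvatinib. DUSP6 fell by 2.99 ± 0.36 (SE, n = 3 per group, adjusted p = 1.23e-04), from 84.3 to 10.5 CPM, ETV5 by 2.54 ± 0.27 (adjusted p = 6.15e-05) and MYC fell by 1.72 ± 0.17 (adjusted p = 2.27e-05). CYP7A1 rose by 6.49 ± 0.65 (adjusted p = 4.21e-05) and ALB by 0.92 ± 0.17 (adjusted p = 0.00115). MKI67 fell by 0.94 ± 0.26 (adjusted p = 0.0144), a call lost without combination replicate 1 (0.0585) or 2 (0.0533) and without a filter (0.0570, range 2.90e-04 to 0.0585). EGR1 fell by 2.47 ± 0.67 (adjusted p = 0.0142), but not without combination replicate 2 (0.0510) or in the 2-group fit (0.0845, range 3.69e-04 to 0.0845). DUSP4 fell by 1.53 ± 0.42 (adjusted p = 0.0121), but not without lenvatinib replicate 2 (0.0504).

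FGFR-MAPK output had 17 of 20 genes lower by both counts (list adjusted p = 1.16e-08) and G2 and mitosis 34 of 36, or 36 over the list alone (4.81e-12). Hepatocyte products had 20 of 30 higher, or 20 higher and 1 lower over the list alone (2.26e-08), fatty acid oxidation 16 of 20 higher and 1 lower by both counts (7.24e-06), and bile acid synthesis 10 of 16 higher, or 11 over the list alone (2.29e-04). For each of these 5 lists adjusted p = 0.394 with an estimated correlation. S phase had 28 of 35 lower, or 32 over the list alone (list adjusted p = 2.17e-08, adjusted p = 0.437 with an estimated correlation). Immediate early genes had 10 of 18 lower and 1 higher, or 12 and 1 over the list alone (1.53e-04), and acute phase genes 8 of 13 higher and 1 lower by both counts (0.00575). Stress response genes had 12 of 22 lower and 3 higher, or 14 and 3 over the list alone (0.00894), and interferon genes 7 of 24 higher and 1 lower, or 6 and 1 over the list alone (0.0133). These 4 lists also had adjusted p = 0.394 with an estimated correlation. Hypoxia genes were lower (9 of 31 lower and 4 higher by both counts, list adjusted p = 0.0225, adjusted p = 0.581 with an estimated correlation), a call lost without lenvatinib replicate 3 (0.0986) or combination replicate 3 (0.0685) and with library totals (0.0516). Fatty acid synthesis (list adjusted p = 0.0237) and WNT targets (0.0272), both with adjusted p = 0.394 with an estimated correlation, lost their calls without combination replicate 2 (0.0592) and without lenvatinib replicate 1 (0.0563) or combination replicate 3 (0.0536), respectively. The fibroblast list was lower (median −0.96, adjusted p = 0.0273, adjusted p = 0.15 with an estimated correlation), but not without any 1 of the 3 lenvatinib tumors (0.0952, 0.0707 and 0.0561), combination replicate 2 (0.0884) or combination replicate 3 (0.0598). In all 3020 genes rose and 3309 fell, or 2293 and 4348 with library totals, which shifted the median of all genes by −0.10. This comparison shares no tumor with H3B-6527 against vehicle. Both called 2706 genes higher (760.3 by chance) and 2884 lower (802.8 by chance), and 0 in opposite directions. The log2 fold changes of the 2 correlated across genes (r = 0.873, rho = 0.879), and genes are not independent replicates.

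Lenvatinib against H3B-6527 tests the difference between the single agents directly. VEGFA was higher with lenvatinib by 1.02 ± 0.14 (SE, n = 3 per group, adjusted p = 1.26e-04), CA9 by 4.52 ± 0.85 (adjusted p = 0.00188), DUSP6 by 4.07 ± 0.39 (adjusted p = 2.39e-05) and MYC by 2.72 ± 0.17 (adjusted p = 1.12e-06). IGFBP1, an insulin-like growth factor binding protein, was at 33.2 CPM with lenvatinib and 0.823 with H3B-6527 (5.46 ± 0.60), against 8.31 with vehicle. CYP7A1 was lower with lenvatinib, at −6.97 ± 0.64 (adjusted p = 1.76e-05), and ALB at −0.96 ± 0.17 (adjusted p = 7.88e-04).

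Hypoxia genes were higher with lenvatinib in 22 of 31 cases and lower in 3, or 23 and 3 over the list alone (median 0.89, list adjusted p = 7.25e-06). FGFR-MAPK output genes were higher in 17 of 20 by both counts (list adjusted p = 1.84e-09), immediate early genes in 14 of 18, or 15 over the list alone (1.48e-06), and G2 and mitosis genes in 26 of 36, or 31 over the list alone (2.86e-09). Hepatocyte products were lower in 18 of 30 and higher in 3, or 19 and 3 over the list alone (1.69e-05), bile acid synthesis lower in 9 of 16, or 10 over the list alone (6.56e-04), and fatty acid oxidation lower in 13 of 20 and higher in 1, or 14 and 1 over the list alone (4.51e-04). Acute phase genes were lower in 8 of 13 and higher in 1 (0.0116), and stress response genes higher in 13 of 22 and lower in 3 (0.00392), each by both counts. WNT targets were higher in 8 of 17 and lower in 2 (0.0212), and ligands higher in 6 of 12 and lower in 2 (0.0254), each by both counts. For all of these lists adjusted p = 0.401 with an estimated correlation, and for S phase (9 of 35 higher, 6 over the list alone, list adjusted p = 1.39e-05) adjusted p = 0.533 with an estimated correlation. The ligand call was lost without H3B-6527 replicate 1 (0.0616). The fibroblast list was higher with lenvatinib (median 0.99, adjusted p = 0.0253, adjusted p = 0.141 with an estimated correlation), but not without H3B-6527 replicate 2 (0.123) or 3 (0.0852), or lenvatinib replicate 1 (0.0897) or 2 (0.0679). Over all genes 3265 were higher with lenvatinib and 3248 lower, or 3989 and 2562 with library totals.

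Non-additivity asks whether the combination differed from the sum of the single-agent effects on the log2 scale. The FGFR-MAPK output list lay above the sum, with 19 of 20 values positive and 4 passing over the list alone (median 0.88, list adjusted p = 8.25e-13, adjusted p = 0.198 with an estimated correlation). ETV5 had a value of 1.33 ± 0.38 (adjusted p = 0.768) and MYC 1.06 ± 0.23 (adjusted p = 0.686, or 0.0248 with DESeq2 and a range of 0.0248 to 1.00), while VEGFA lay at −0.02 ± 0.19 (adjusted p = 0.997). The mitochondrial genome list was also above the sum, with 6 genes over the list alone (median 0.55, list adjusted p = 2.31e-12, adjusted p = 0.198 with an estimated correlation), as were WNT targets, with 1 (median 0.27, list adjusted p = 0.00331, adjusted p = 0.198 with an estimated correlation). The median of WNT targets was 0.08 without H3B-6527 replicate 1, 0.17 without lenvatinib replicate 1 and 0.13 without combination replicate 3. YAP targets (2 over the list alone, list adjusted p = 0.00331, adjusted p = 0.249 with an estimated correlation) lost the call without H3B-6527 replicate 2 (0.139). Immediate early genes (1 over the list alone, list adjusted p = 0.00352) lost it without lenvatinib replicate 1 (0.128) or H3B-6527 replicate 2 (0.0718), and cholesterol synthesis (list adjusted p = 0.00402) without lenvatinib replicate 3 (0.0802) or H3B-6527 replicate 2 (0.0555). Fatty acid oxidation lay below the sum (median −0.20, or −0.10 without H3B-6527 replicate 1 and −0.325 without H3B-6527 replicate 3, list adjusted p = 0.0211) and lost the call without H3B-6527 replicate 1 (0.506) or 2 (0.0718), vehicle replicate 3 (0.121), lenvatinib replicate 2 (0.0510) or combination replicate 3 (0.202). These last 3 lists had adjusted p = 0.688 with an estimated correlation. No single gene passed with edgeR (0 of 15836, with 854 at an unadjusted p under 0.05 and 18 called by DESeq2).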

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

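The test of a uniformly weaker response was chosen only after the result was seen, and the others were written before.

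These 7 gene lists were picked out because the combination differed from the sum of the single-agent effects in a direct test of that difference. FGFR-MAPK output (list adjusted p = 8.25e-13), the mitochondrial genome (2.31e-12), WNT targets (0.00331), YAP targets (0.00331), immediate early genes (0.00352) and cholesterol synthesis (0.00402) lay above the sum, and fatty acid oxidation (0.0211) lay below it. With an estimated correlation 0 of them passed. Permuting the labels gave as many list calls in 63 of 100 draws (7 real, up to 14 in another draw). The draws mix tumors given H3B-6527 with the others, so the effect of that drug enters the contrast or its spread. They therefore do not measure chance for that count, and chance stays open. With 0 genes called in the real data, all 100 of 100 draws give as many, which says nothing about chance. A draw can also set tumors given H3B-6527 against the others. The draw with the most gene calls (9551) may therefore reflect the drug, and its tumors were not recorded.

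The FGFR-MAPK output list, with DUSP6, ETV5 and MYC among its members, was higher with the combination than with H3B-6527 alone (median log2 fold change 0.64), a call that was lost with an estimated correlation (adjusted p = 0.327) in a comparison where fry called 0 lists and other splits gave up to 14 list calls against 12 real. No 1 library carried this, as the lowest median with any library left out was 0.425, and thinning all libraries to the smallest total kept 91.5% of it. A response to H3B-6527 that was weaker by the same share (31.6%) for every gene stays open, since the lists disagree in the non-additivity contrast, which removes the effect of lenvatinib alone. Of 11 other lists called with H3B-6527, 5 had the value that share gives inside the range of medians with a library left out. Hepatocyte products were 1 of these, at −0.251 (−0.383 to −0.0841) where that share gives −0.36. The rest had it outside. Among them S phase (−0.168, range −0.386 to 0.168, against 0.173 from that share) and G2 and mitosis (−0.216, range −0.399 to 0.144, against 0.255) had the opposite sign. Both turned positive without H3B-6527 replicate 3. Acute phase (0.0134, range −0.104 to 0.165, against −0.274) and interferon genes (0.0229, range −0.0879 to 0.0978, against −0.136) also had the opposite sign, with ranges that span both signs. For stress response genes the value from that share and the upper end of the range were both 0.193 as rounded. Such ranges are not confidence intervals. A partial return of MAP kinase signalling when lenvatinib is added could also account for the pattern. Exposure to H3B-6527 in the combination tumors and the time after the last dose were not measured in these data, and the result rests on the same libraries in which it was noticed.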

How the results depend on the processing

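Fits of 3 groups, library totals, and the list tests under other filters and scalings were chosen only after the result was seen.

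The number of genes called stayed within 1.5 times its value for H3B-6527 against vehicle (6361 to 8618), the combination against vehicle (7351 to 9728) and the combination against lenvatinib (5593 to 7770) under each full-set alternative, while the split by direction moved with library totals. Lenvatinib against H3B-6527 gave 4389 to 6784. For lenvatinib against vehicle, where edgeR called 0, DESeq2 called 245, voom 525, a fit without a low-count filter 41, a fit of the 2 groups 189, and a fit without the H3B-6527 group 173. A fit without the combination group called 0. The first 3 settings change the test or the genes tested, and for the fits that leave out the H3B-6527 tumors the shared spread no longer includes that group. For the combination against H3B-6527, where edgeR called 2, DESeq2 called 98, voom 5, no filter 13 and the 2-group fit 1. For non-additivity DESeq2 called 18, and the other tools called 0. Beyond what such construction shows, the cause was not tested.

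With an estimated correlation 0 tumor lists passed in any of the 7 comparisons, and fry called 0 for lenvatinib against vehicle, the combination against H3B-6527 and non-additivity. In the 2-group fit of lenvatinib and vehicle 15 tumor lists passed, with 0 by an estimated correlation and 0 by fry. The fibroblast list, whose tested members the tumor cells can express, was the 1 host list called in each of 4 comparisons. There the estimated correlation gave 0 host lists, fry gave 3 for H3B-6527 against vehicle and 4 in each of the others, and a fit without a filter gave 0. The stricter filter gave 1 host list for lenvatinib against vehicle, library totals gave 2 for the combination against vehicle and 0 for the combination against lenvatinib, and a fit without the combination group gave 2 for lenvatinib against H3B-6527.

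With each library left out in turn, edgeR called 0 to 13 genes for lenvatinib against vehicle (13 without vehicle replicate 2), 0 to 16 for the combination against H3B-6527 and 0 to 0 for non-additivity. Where a group keeps 2 tumors they are assumed to vary like the other groups. Tumor lists called ran from 3 (without H3B-6527 replicate 2) to 11 (without H3B-6527 replicate 1) for non-additivity. Host lists ran from 0 to 1 for H3B-6527 against vehicle, the combination against H3B-6527 and the combination against lenvatinib, and from 0 to 2 for the combination against vehicle and lenvatinib against H3B-6527. The S phase and G2 and mitosis lists reversed without H3B-6527 replicate 3. Between the combination and H3B-6527 they became positive at adjusted p = 0.284 and 0.115, with ranges over left-out libraries of 7.61e-16 to 0.371 and 1.17e-11 to 0.371. In the non-additivity contrast they turned at adjusted p = 0.0144 and 0.0117, with ranges of 1.33e-09 to 0.756 and 2.18e-07 to 0.848.

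Of the values for named genes under other settings, 1558 kept their side of the threshold, 42 passed it, 7 no longer did and 2 moved. With a library left out 1295 kept it, 11 passed, 12 no longer did, 38 moved and none reversed. For lists 1458 kept their side, 69 passed it, 148 no longer did and 46 moved under other settings, and with a library left out the numbers were 1276, 50, 55 and 103, with the 4 reversals above. Depth limits statements on genes near the floor of 0.126 CPM, such as CYP7A1 in vehicle tumors and most host markers.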

Other observations

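The gene lists described here, the test of host reads, the test of lenvatinib itself and the test of untreated RNA mixed into replicate 3 were chosen only after the result was seen.

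Genes for building ribosomes were lower with both H3B-6527 treatments, on lists put together after seeing the data. Of 32 ribosome assembly and RNA polymerase I genes, 31 fell with H3B-6527 against vehicle (median log2 fold change −0.98, list adjusted p = 4.96e-14, adjusted p = 0.260 with an estimated correlation) and 30 with the combination (median −1.08, list adjusted p = 1.85e-14, adjusted p = 0.227 with an estimated correlation). With lenvatinib the list was also lower, though 0 of its genes passed (median −0.35, 2 of 32 values positive, list adjusted p = 2.93e-19, adjusted p = 0.213 with an estimated correlation). Of 82 ribosomal protein genes, 73 fell with H3B-6527 (median −0.56, list adjusted p = 4.96e-14, adjusted p = 0.279 with an estimated correlation). With the combination 10 fell and 1 rose (median −0.17, list adjusted p = 0.00515, adjusted p = 0.651 with an estimated correlation). With lenvatinib 79 had positive values (median 0.21, list adjusted p = 2.86e-13, adjusted p = 0.354 with an estimated correlation). All these directions held with library totals. Histone genes fell in 39 of 61 cases and rose in 1 with H3B-6527 (median −0.77, list adjusted p = 3.09e-08, adjusted p = 0.315 with an estimated correlation).

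Liver functions outside the lists fixed beforehand also moved. Complement and coagulation genes rose in 34 of 42 cases and fell in 2 with H3B-6527 (median 1.32, list adjusted p = 2.03e-10, adjusted p = 0.260 with an estimated correlation), and drug metabolism genes rose in 22 of 41 and fell in 3 (median 0.99, list adjusted p = 1.65e-04, adjusted p = 0.260 with an estimated correlation). Amino acid breakdown genes rose in 26 of 41 and fell in 6 (median 0.69, list adjusted p = 1.88e-05, adjusted p = 0.260 with an estimated correlation). Notch pathway genes, where HEY1 and LFNG had large falls, had 9 of 20 lower and 4 higher and did not pass (list adjusted p = 0.115).

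The hypoxia list was higher with lenvatinib in 2 comparisons that share no tumor, lenvatinib against vehicle and the combination against H3B-6527, but both calls were lost with an estimated correlation (adjusted p = 0.216 and 0.327), fry called 0 lists, no member passed over all genes, and across all genes the 2 sets of fold changes correlated weakly (r = 0.166, rho = 0.226, 59.5% of the same sign, genes not independent). The lowest list median with any library left out was 0.38, and after thinning to the smallest total at least 87.0% of the median was kept, which argues against a single library or depth. The 143 host markers under 10 CPM with vehicle gained 16.1 CPM together, while VEGFA gained 64 CPM. Among markers already higher with vehicle, APOE (713 CPM, from 1820) and RELN (158, from 2790) gained more than VEGFA. VTN (33.5), PLIN4 (22.4) and ARG1 (18.6) gained less. ARG1 is also a member of the amino acid breakdown list above. Over all tumors the endothelial genes CDH5 and KDR had 3 and 5 counts, and the macrophage gene C1QA had 0 counts. The gains of APOE, RELN, VTN, PLIN4 and ARG1 can come from the tumor cells. No change in host cells is read from these gains. How far mouse reads can count under human symbols is not known here. Markers near the floor therefore do not exclude reads from host cells. The lower of the 2 medians was 0.52, but the pattern was picked from these medians, so they decide nothing about an effect of lenvatinib itself, which stays open. Oxygen, vessel density and tumor size were not measured in these data, and the host endothelium could not be followed.

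The 3 tumors given H3B-6527 alone responded unequally. Their slopes were taken along the profile of the combination against lenvatinib, a comparison that holds none of these tumors. The genes of the profile were called in the fit of all 12 libraries, whose shared spread does include them. The slopes were 1.28, 1.06 and 0.826, with 0.826 in replicate 3, the smallest library. After thinning to equal totals 102% of the range of the slopes remained, so depth does not explain it. Untreated tumor RNA mixed into replicate 3 would need 1 share for all genes, but the share had an upper quartile of 12.6% over genes lowered by the drug and a lower quartile of 45.3% over genes raised by it. The labels give the same dose and the same time after the last dose for all 3. Departures from these, or differences in drug exposure, may remain and were not tested.

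The 6 tumors of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. Each other split keeps 2 tumors of 1 group together with 1 of the other, so a real difference stays partly in the contrast. The rest of it adds to the spread within the groups. Calls in the other splits therefore do not measure chance, for genes or for lists. For genes called, the real value and the highest of the other splits were 7829 and 0 for H3B-6527 against vehicle (1 split as large, the real one included), 0 and 0 for lenvatinib against vehicle (10), 7930 and 0 for the combination against vehicle (1), 6329 and 0 for the combination against lenvatinib (1) and 6513 and 0 for lenvatinib against H3B-6527 (1). For the combination against H3B-6527 they were 2 and 640 (2 splits). The split with 640 set H3B-6527 replicate 1 with combination replicates 1 and 2 against the other 3. It followed the slope along the profile above, a profile that uses the combination tumors. The slopes were 1.28, 1.16 and 1.13 on that side. They were 1.06 and 0.826 in H3B-6527 replicates 2 and 3, and 0.96 in combination replicate 3. For tumor lists called, the real value and the highest of the other splits were 12 and 13 for H3B-6527 against vehicle (3 splits), 9 and 9 for lenvatinib against vehicle (3) and 13 and 11 for the combination against vehicle (1). They were 12 and 14 for the combination against H3B-6527 (4), 13 and 14 for the combination against lenvatinib (2) and 12 and 14 for lenvatinib against H3B-6527 (2).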
